A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

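The series measured messenger RNA of budding yeast (Saccharomyces cerevisiae) on 6 2-colour arrays. Each array compared RNA of cells grown with air (aerobic) with RNA of cells grown with little oxygen (hypoxic). On 3 arrays both cultures were wild type, and on 3 both lacked HAP1, the gene of a heme-responsive transcription factor. According to the series description, the replicates of a strain were independent cultures from different days. The labels put the hypoxic RNA in Cy5 on replicates 1 and 3 of each strain and in Cy3 on replicate 2, so the dyes were swapped on 1 array of each strain.

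Per the labels, RNA was primed from its poly(A) tails and spots were quantified with GenePix 5.0. The background correction, spot filters and normalization that followed are not given in the sources used here, and the spot intensities were not analysed here. The values deposited by the authors were log10 ratios, aerobic over hypoxic. The titles state this direction, and it was read as applying to every array. The replicate 2 arrays, with swapped dyes, correlated across genes with the other arrays of their strain at r from 0.454 to 0.575, above the level of 0.3 set beforehand for taking the ratios as already turned the same way. The base of the logarithm was read from the values. With 10 as the base, 242 of 36476 values were exact ratios of whole numbers with a denominator of up to 30 (relative tolerance 7e-08), against 6 with base 2 and 5 with base e. The design written beforehand assumed log2 ratios. All values were therefore converted to log2 and turned to hypoxic over aerobic, so that a positive value means more RNA in hypoxia. The array medians of the deposited log10 values lay between 0.00540 and 0.0218, so the arrays had been centred close to 0. The overall sign was also read on 6 marker genes that textbooks place higher in hypoxia. In wild type HEM13 and TIR1 of these were higher, ANB1, whose spot may share signal with its near-identical copy HYP2, was lower and 3 did not pass the test. The direction of these markers is not a finding.

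The table held 6282 rows, each with its own systematic gene name, so no gene had several rows. Whether several spots of a gene were combined before deposit cannot be seen from these rows. Between 15 (wild-type replicate 1) and 678 (hap1 deletion replicate 1) values were missing per array. The RefSeq gene table of assembly R64 gave symbols for 5707 of the rows, and the other 575 kept their systematic names. The build behind the array design is not given in the sources used here, so no coordinates are reported. The 6208 genes with at least 2 values in each strain were tested, and 74 were not.

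The mean log2 ratio of each strain and the difference between the strains (hap1 deletion minus wild type, which is the interaction of strain and oxygen) were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided). One residual spread per gene was shared by both strains, with 4 residual degrees of freedom, a prior of 2.97 degrees of freedom and a prior SD of 0.404. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Values are given as the mean ± SD over the arrays of a strain, and differences with limma's moderated standard error (SE). Only 3 arrays per strain limit the precision. In simulated data each gene had its moderated spread, and of 6208 genes 50 were changed at each size. Of wild-type changes of 1 on the log2 scale 44% were called, 92% at 2 and 98% at 3. For the difference between strains 2% were called at 1, 80% at 2 and 92% at 3. False calls numbered 7 for wild type and 6 for the difference, leaving aside the changed genes and 1 gene list that was shifted by 1 in wild type. The simulated noise was normal and independent between genes and arrays, so shifts shared by the genes of an array were not represented. The shares called and the false calls may therefore be too favourable for the measured arrays.

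A set of 36 gene lists was fixed before the data were examined. They covered sterol synthesis, sterol import, heme synthesis, textbook Hap1-activated and Rox1-repressed genes, DAN and TIR mannoproteins, seripauperins, the respiratory chain, ATP synthase, the tricarboxylic acid cycle, glycolysis, gluconeogenesis, hexose transporters, cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, general stress, chaperones, iron, antioxidant defence, fatty acid synthesis, beta-oxidation, amino acid synthesis, sulfur metabolism, phosphate, zinc, glycerol, other cell wall proteins, histones, the proteasome, a-specific, alpha-specific and pheromone genes, meiosis, the direction markers, and oxygen and heme regulators. The mating and meiosis lists were chosen as markers of cells of another mating type or ploidy. Both cultures on an array were of the same strain, so the ratios cannot show a mating type or ploidy that both shared. List members were matched by symbol or synonym, and 1 found no match. Each list with at least 4 measured members was tested with limma's camera on the moderated statistics (preset correlation between genes 0.01) and adjusted over the 36 lists of a comparison. Camera with an estimated correlation and fry ran on the 5301 genes with a value on all 6 arrays. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone.

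The genes named in the text follow a rule set beforehand. Within a strain these are the 8 largest rises and the 8 largest falls among genes past the threshold with all 3 values of the same sign. For the difference, they are the 10 largest in each direction among genes past the threshold with all 6 values. If fewer than 5 passed, the 5 smallest p-values were taken and said not to have passed. For each list up to 4 members with the largest change may be named, plus a fixed set of oxygen-responsive genes. Uncharacterised reading frames that overlap a named gene were left out. A gene named outside this rule is said to have been chosen after its values were seen. Alternatives to these choices covered centring and scaling of the arrays, a dye term, the replicate number as a block, the handling of missing values, the variance prior, array weights, the sign of the replicate 2 arrays, leaving out arrays, and thresholds. Exact permutation tests used Python 3.11.15 with numpy 2.4.6.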

Results

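The hypoxic response was measured in wild-type yeast (3 arrays) and in a strain lacking HAP1 (3 arrays). Each array gave 1 ratio per gene of hypoxic over aerobic RNA, and 6208 genes were tested. The HAP1 spot itself read 0.84, 0.50 and 1.10 on the wild-type arrays and 0.47, 0.56 and 0.72 on the deletion arrays (log2). Because both cultures on an array were of the same strain, this ratio cannot show whether the gene was missing. Ratios correlated across genes between the arrays of a strain at r from 0.412 to 0.539 in wild type and from 0.329 to 0.575 in the deletion strain. Between arrays of different strains r ran from 0.0971 to 0.538, so the arrays did not group cleanly by strain. Wild-type replicate 1 correlated more with hap1 deletion replicate 3 (r = 0.538) than with either other wild-type array. Genes are not independent replicates.

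The first comparison asked which genes responded to low oxygen in wild-type cells. Hypoxia sharply lowered YHB1, the flavohemoglobin that detoxifies nitric oxide, and CYC1, the main cytochrome c. YHB1 (YGR234W) changed by -5.06 ± 0.44 on the log2 scale (SD, n = 3), a 33.4-fold fall, and CYC1 (YJR048W) by -4.85 ± 0.07 (SD, n = 3), a 28.9-fold fall. OLE1 (YGL055W), the fatty acid desaturase, fell by 4.63 and NDE1, the external mitochondrial NADH dehydrogenase, fell by 4.53. Among genes with all 3 values, the largest rises were in cell wall families of anaerobic growth, led by TIR2 at 4.67 ± 1.16 (SD, n = 3). In limma's moderated test 119 genes were higher and 144 lower in hypoxia at a Benjamini-Hochberg adjusted p under 0.05, and 5945 did not pass. With a change of at least 2-fold these counts were 108 and 119. Arrays centred on their medians and then scaled to the same spread gave 180 and 171. The share of higher genes among the calls went from 45.2% to 51.3%, and centring alone moved it to 50.9%.

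Of 13 textbook Hap1-activated genes, 5 fell in wild type, none rose and 8 did not pass, and 8 fell adjusted over the list alone. The 5 were YHB1, CYC1, CYC7 (the minor cytochrome c, -2.15 ± 1.20), HMG1 (an HMG-CoA reductase of sterol synthesis, -2.17 ± 1.07) and CYB5 (an electron donor in lipid synthesis, -1.91 ± 0.66). Falls numbered 2 without wild-type replicate 2 or 3 or hap1 deletion replicate 2, and 3 without hap1 deletion replicate 3. The median was -0.997 (camera adjusted p = 2.13e-17, and adjusted p = 0.231 with an estimated correlation). ROX1, the repressor of hypoxic genes, had a value of -0.92 ± 0.67 and did not pass (limma adjusted p = 0.0931), and CYT1, cytochrome c1, had -1.40 ± 0.77 (adjusted p = 0.0558). CYB2 had -0.53 ± 0.68.

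Of 25 genes of the respiratory chain, 5 fell and 20 did not pass, and 15 fell adjusted over the list alone. The falls included CYC1, NDE1 and COX5A, the aerobic form of a cytochrome oxidase subunit (-1.79 ± 1.04). COX5B, its hypoxic counterpart, had 2.15 ± 1.44 and did not pass (limma adjusted p = 0.0573). Without wild-type replicate 2 or 3 or hap1 deletion replicate 2, 1 fall was called, and without hap1 deletion replicate 3 there were 3. The respiratory median was -1.004 (camera adjusted p = 1.06e-08, and adjusted p = 0.483 with an estimated correlation). By array it was -0.23, -1.24 and -1.52 for replicates 1 to 3.

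Of 24 ergosterol biosynthesis genes, 5 fell in wild type (HMG1, ERG13, ERG8, MVD1 and CYB5), and 19 did not pass, while 10 fell adjusted over the list alone. ERG13, HMG-CoA synthase, changed by -1.80 ± 0.10 and ERG8, phosphomevalonate kinase, by -1.63 ± 0.41. Some later enzymes varied widely between arrays: ERG5 read -0.04, -3.75 and -4.06 and ERG3 read 0.73, -2.61 and -2.13 on replicates 1 to 3, and neither passed. ERG11 (0.64, -1.70 and -1.93) did not pass either. No fall was called without wild-type replicate 2, and 1 was called without wild-type replicate 3 or hap1 deletion replicate 2. The ergosterol median was -0.68 (camera adjusted p = 1.13e-06, and adjusted p = 0.483 with an estimated correlation). By array it was -0.04 on replicate 1, -0.88 on replicate 2 and -0.93 on replicate 3.

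The families that rose encode cell wall proteins. Of 23 seripauperin (PAU) genes, 19 rose and 4 did not pass, and 22 rose adjusted over the list alone. The largest were PAU16 (4.43 ± 2.16), PAU12 (4.35 ± 1.41), PAU13 (4.30 ± 1.24) and PAU11 (4.27 ± 1.64), followed by PAU4 and PAU5. Members of this family are nearly identical in sequence, so spots may share signal and the values of single members are uncertain. Rises numbered 2 without wild-type replicate 1, 0 without wild-type replicate 2 and 11 without hap1 deletion replicate 2. The PAU median was 2.72 (camera adjusted p = 1.49e-45, and adjusted p = 0.231 with an estimated correlation). Of 8 DAN and TIR mannoproteins, 6 rose, also adjusted over the list alone, including TIR2, TIR4 (3.47 ± 0.85), TIR3 and TIR1 (2.44 ± 0.99). Without wild-type replicates 1, 2 and 3 in turn there were 2, 0 and 1 rises. The median was 2.54 (camera adjusted p = 8.31e-16, and adjusted p = 0.231 with an estimated correlation). DAN1 had 0.71 ± 0.63 (SD, n = 2) and did not pass.

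HEM13, the oxygen-requiring coproporphyrinogen oxidase of heme synthesis and, like TIR1, a direction marker, rose by 3.06 ± 0.82 (limma adjusted p = 0.0116). It was the only riser among 8 heme synthesis genes and among 8 textbook Rox1-repressed genes, where CYC7 and ANB1 fell and 5 did not pass. Adjusted over the list alone, the Rox1-repressed list had 2 rises and 3 falls. ANB1, a hypoxic translation factor gene, changed by -1.04 ± 0.47, and its near-identical aerobic copy HYP2, looked up after the values were seen, by -1.93 ± 0.40. The ANB1 spot may share signal with HYP2, so its fall is uncertain. AAC3, the hypoxic ADP/ATP carrier, read -0.32, 2.55 and 1.26 on the 3 arrays and did not pass. The lists of heme synthesis and Rox1-repressed genes did not pass (camera adjusted p = 0.0541 and 0.585). The heme list passed without wild-type replicate 1 or 2 (camera adjusted p = 0.00560 and 0.0316) and the Rox1-repressed list without wild-type replicate 1 (camera adjusted p = 0.0215). The Rox1-repressed genes had a median of -0.09 and a mean of 0.26.

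In the tricarboxylic acid cycle 3 of 15 genes rose and none fell, and 6 rose adjusted over the list alone. The 3 over all genes were aconitase, ACO1 (1.95 ± 0.19), and both subunits of isocitrate dehydrogenase, IDH1 (1.68 ± 0.33) and IDH2 (1.67 ± 0.21). None was called in limma's test without any 1 of the wild-type replicates. The median of the cycle was 0.66 (camera adjusted p = 2.74e-07, and adjusted p = 0.231 with an estimated correlation). In glycolysis and fermentation 3 of 21 genes rose, over all genes and adjusted over the list alone, namely the hexose kinases GLK1 (2.92) and HXK1 (1.78) and the mutase GPM1 (0.79). Its median was 0.32 (camera adjusted p = 0.000856, and adjusted p = 0.231 with an estimated correlation). In fatty acid synthesis OLE1 and the elongase ELO1 (-2.03 ± 0.53) fell among 13 genes, over all genes and adjusted over the list alone. Its median was -0.30 (camera adjusted p = 0.00687, and adjusted p = 0.231 with an estimated correlation).

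Among 26 general stress genes 4 rose in wild type and 22 did not pass, with 16 rises adjusted over the list alone. The largest was GPH1, glycogen phosphorylase (4.62, n = 2). GSY1, YGP1 and TFS1 had means of 4.04, 3.74 and 3.58 and did not pass. No rise was called without any 1 of the wild-type replicates or without hap1 deletion replicate 2, and 10 were called without hap1 deletion replicate 3. The stress median was 1.75 (camera adjusted p = 2.93e-10, and adjusted p = 0.334 with an estimated correlation), and by array it was 2.29, 1.54 and 0.88. Among 22 chaperones 4 rose, with 7 adjusted over the list alone, including SIS1 (1.56) and HSP60 (1.55), and none was called without any 1 of the wild-type replicates or without hap1 deletion replicate 2. The chaperone median was 0.69 (camera adjusted p = 1.48e-05, and adjusted p = 0.334 with an estimated correlation).

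Ribosome biogenesis genes moved the other way: 19 of 95 fell, 2 rose and 74 did not pass, with 63 falls and 3 rises adjusted over the list alone. No fall was called without any 1 of the wild-type replicates or without hap1 deletion replicate 2, and 34 were called without hap1 deletion replicate 1. The median of the biogenesis list was -0.89 (camera adjusted p = 2.04e-21, and adjusted p = 0.334 with an estimated correlation). Of 132 cytosolic ribosomal protein genes 2 fell and 1 rose, and none passed adjusted over the list alone. Their median was -0.37 (camera adjusted p = 4.71e-08, and adjusted p = 0.512 with an estimated correlation). In the iron regulon 4 of 26 genes fell, over all genes and adjusted over the list alone, while the list as a whole did not pass (camera adjusted p = 0.213, and 0.00662 without wild-type replicate 1). They were the ferric reductase FRE1 (-2.66 ± 0.93), the uptake oxidase FET3 (-2.60 ± 0.80), its permease FTR1 (-1.65) and heme oxygenase HMX1 (-1.41), and without wild-type replicates 1, 2 and 3 and hap1 deletion replicate 2 there were 1, 0, 0 and 1 falls. The remaining genes among the 8 largest falls were PRM7 (-3.24 ± 1.12), a pheromone-regulated membrane protein, and IZH1 (-2.83 ± 0.46), a membrane protein of zinc homeostasis.

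The wild-type counts depended on single arrays. Against 263 calls in all, 27 were made without wild-type replicate 1, 2 without wild-type replicate 2, 24 without wild-type replicate 3 and 39 without hap1 deletion replicate 2, and only YHB1 and CYC1 kept the call whichever of the 6 arrays was left out. A dye term left 28 higher and 14 lower genes, with no call among the ribosome biogenesis, general stress and chaperone genes.

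The second comparison asked for the same response in cells lacking HAP1. Here hypoxia raised the sterol pathway as well as the cell wall families. Of 24 ergosterol biosynthesis genes 15 rose, none fell and 9 did not pass, with 21 rises adjusted over the list alone. ERG28 (YER044C), a scaffold of the sterol demethylation complex, rose by 3.11 ± 0.24 (SD, n = 3), ERG26 (YGL001C), a sterol dehydrogenase, by 2.70 ± 0.15 and ERG2 (YMR202W), a sterol isomerase, by 2.09 ± 0.03. YHB1 (0.05 ± 0.19), CYC1 (0.04 ± 0.53) and OLE1 (1.37 ± 0.31) did not pass. In limma's test 155 genes were higher and 113 lower at a Benjamini-Hochberg adjusted p under 0.05, and 5940 did not pass. Arrays centred and then scaled to the same spread gave 154 and 71. The share of higher genes among the calls went from 57.8% to 68.4%, and centring alone moved it to 64.1%.

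The ergosterol list median in the deletion strain was 1.53 (camera adjusted p = 1.12e-26, and adjusted p = 0.380 with an estimated correlation), and by array it was 1.57, 1.47 and 1.49. Its 15 rises became 6, 2 and 2 without hap1 deletion replicates 1, 2 and 3. ERG5 (2.86 ± 0.46), ERG3 (2.14 ± 0.15) and ERG11 (1.87 ± 0.26) lay above 0 on all 3 arrays without passing, and ERG25 (0.52 ± 0.36), HMG1 (0.72 ± 0.45) and HMG2 (0.18 ± 0.47) did not pass. The test used 1 residual spread for both strains. The wide spread of ERG5, ERG3, ERG11 and OLE1 between the wild-type arrays therefore entered their tests in the deletion strain. The sterol regulators UPC2 (-0.28 ± 0.19), ECM22 (-0.24 ± 0.89, n = 2), MOT3 (-0.16 ± 0.02) and SUT1 (-0.72 ± 0.69) did not pass in this strain, and none of them passed in wild type. Of the 13 textbook Hap1-activated genes 2 rose, CYB5 (2.06 ± 0.24) and NCP1, the cytochrome P450 reductase (0.86), none fell and 11 did not pass. Adjusted over the list alone, 3 rose. Without any 1 of the deletion replicates none was called in limma's test over all genes, and without wild-type replicate 2 or 3, 1 was. Their median was 0.37 (camera adjusted p = 0.0159, and adjusted p = 0.599 with an estimated correlation), and the list did not pass without hap1 deletion replicate 1 or 3 (camera adjusted p = 0.0871 and 0.0827). Of 25 respiratory chain genes none passed limma's test, over all genes or adjusted over the list alone (3 had an unadjusted p under 0.05), with NDE1 at -2.08 ± 0.24 and a list median of 0.11 (camera adjusted p = 0.336).

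Of 23 PAU genes 21 rose, with 22 adjusted over the list alone, and the median was 4.57 (camera adjusted p = 9.60e-101, and adjusted p = 0.380 with an estimated correlation). PAU6 had the largest rise, 7.51 ± 2.53, with values of 10.24, 7.05 and 5.25. PAU4 (5.26 ± 0.04), PAU16, PAU11, PAU13 and PAU20 followed, each at 4.95 or above. Of the 8 DAN and TIR genes 5 rose, led by DAN4 (5.14 ± 0.82), with 6 adjusted over the list alone and 3, 3 and 2 without deletion replicates 1, 2 and 3. They had a median of 2.94 (camera adjusted p = 2.48e-15, and adjusted p = 0.380 with an estimated correlation). NCE103, a carbonic anhydrase, rose by 5.47 ± 1.59. HEM13 rose by 1.97 ± 0.13 (limma adjusted p = 0.0198).

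Among genes with all 3 values, ribosome synthesis genes made up 4 of the 8 largest falls. NOP13 (-1.93 ± 0.09), ECM1 (-1.92 ± 0.41), TSR1 (-1.90 ± 0.94) and NSR1 (-1.87 ± 0.42) all act in ribosome assembly or in the nucleolus. The ribosome biogenesis list had 14 falls among 95 genes and 81 genes that did not pass, with 51 falls and 1 rise adjusted over the list alone. Without hap1 deletion replicate 2 or 3 no fall was called, without wild-type replicate 1 or 2 there were 9, and without wild-type replicate 3 there were 5. Its median was -0.74 (camera adjusted p = 7.50e-15, and adjusted p = 0.599 with an estimated correlation). Of 132 cytosolic ribosomal protein genes 3 fell, none of them adjusted over the list alone, with a median of -0.45 (camera adjusted p = 8.58e-09, and adjusted p = 0.599 with an estimated correlation). FET3 (-2.40 ± 0.43), ELO1 (-2.12 ± 1.17) and IMD2, an IMP dehydrogenase of guanine nucleotide synthesis (-1.99 ± 0.29), completed the largest falls that were named, and the remaining 1 of the 8 is a dubious reading frame that overlaps NSR1.

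In the iron regulon 4 of 26 genes fell (FET3, ENB1, ARN2 and FRE3, which serve iron uptake), with 7 adjusted over the list alone. There were 1, 0 and 0 falls without deletion replicates 1, 2 and 3, and 2 without wild-type replicate 2 or 3. The iron median was -0.46 (camera adjusted p = 0.00230, and adjusted p = 0.599 with an estimated correlation), and the list did not pass without hap1 deletion replicate 3 (camera adjusted p = 0.0580). In the zinc regulon 2 of 6 genes fell, over all genes and adjusted over the list alone, the transporters ZRT1 (-1.42) and ZRC1 (-0.96). Its median was -0.58 (camera adjusted p = 0.0167, and adjusted p = 0.419 with an estimated correlation), and it did not pass without hap1 deletion replicate 3 (camera adjusted p = 0.0827). None of the 26 general stress genes passed in limma's test over all genes, where 7 had an unadjusted p under 0.05, and 2 rose adjusted over the list alone. The largest value was that of HSP12 (4.02 ± 0.89). The stress median was 1.13 (camera adjusted p = 0.00235, and adjusted p = 0.599 with an estimated correlation), and by array it was -0.16, 0.74 and 2.37. Without hap1 deletion replicate 3 the stress list did not pass (camera adjusted p = 0.389). In the tricarboxylic acid cycle none of 15 genes passed limma's test (4 had an unadjusted p under 0.05, and camera's adjusted p was 0.419), and among 22 chaperones CPR6 rose (camera adjusted p = 0.149, and 0.0217 without hap1 deletion replicate 2).

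Against 268 calls in the deletion strain, 136 were made without wild-type replicate 2, 141 without wild-type replicate 3, and 128, 30 and 49 without hap1 deletion replicates 1, 2 and 3. PAU calls stayed at 15 or above in these fits, and 27 genes, among them ERG28 and ERG26, kept the call whichever of the 6 arrays was left out. With all arrays, a dye term left 90 higher and 31 lower genes, and the strain fitted alone gave 73 and 11.

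The responses of the strains overlapped. The calls of both strains shared 105 genes, of which 53 were higher in both and 47 lower in both. Independent lists of these sizes would share 2.97 and 2.62. The lists were not independent, because both tests used the same residual spread for a gene, so a gene with a small spread could be called in both. With each strain fitted alone wild type had 2 calls, so at most 2 could then be shared. The mean responses correlated across genes at r = 0.549 (Spearman's rho = 0.518). The other 5 genes were lower in hypoxia in wild type and higher in the deletion strain: the sterol genes ERG13, ERG8, MVD1 and CYB5, and PRM10, a pheromone-regulated membrane protein, named after its values were seen. Without wild-type replicates 1, 2 and 3 in turn the strains shared 16, 0 and 19 calls, of which 7, 0 and 1 were in opposite directions. Without hap1 deletion replicates 1, 2 and 3 they shared 91, 13 and 29, of which 3, 0 and 1 were in opposite directions.

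**Figure D1:**
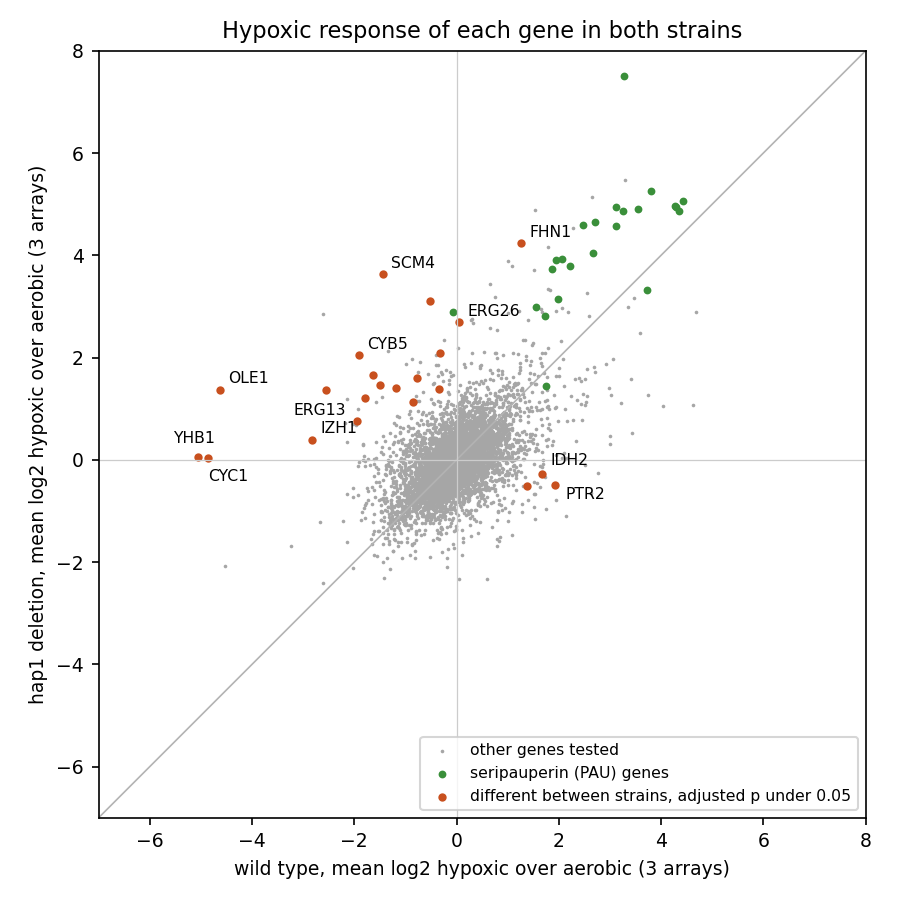
Mean log2 ratio, hypoxic over aerobic, of each of the 6208 genes tested in wild type (horizontal) and in the hap1 deletion strain (vertical), 3 arrays each, with the line of equal response. The 22 genes that differed between the strains are in orange and the PAU genes in green, and YHB1 and CYC1 lie near -5.06 and -4.85 in wild type and near 0.05 and 0.04 in the deletion strain.

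The third comparison tested which responses differed between the strains. The sterol pathway led it, since 18 of 24 genes had a mean below 0 in wild type and 23 had a mean above 0 in cells lacking HAP1. YHB1 and CYC1 showed no fall in the deletion strain, with differences of 5.11 (SE 0.30) and 4.89 (SE 0.32) on the log2 scale. No array compared the strains directly. For these and all other genes, a difference in ratio cannot tell a change of aerobic RNA from a change of hypoxic RNA. OLE1 differed most, by 6.01 (SE 0.70), from -4.63 ± 1.49 in wild type to 1.37 ± 0.31 in the deletion strain (SD, n = 3 each). In limma's test of the difference 19 genes were more positive in the deletion strain and 3 more negative at a Benjamini-Hochberg adjusted p under 0.05, all by at least 2-fold, and 6186 did not pass. An unadjusted p under 0.05 was found for 495 genes. Of the 19, 17 had a mean below 0 in wild type and above 0 in the deletion strain.

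Of 24 ergosterol biosynthesis genes 9 were more positive in the deletion strain, none more negative and 15 did not pass, with 21 more positive adjusted over the list alone. They were CYB5 (difference 3.97, SE 0.38), ERG28 (3.63, SE 0.36), ERG8 (3.29, SE 0.30), ERG13 (3.002, SE 0.23), MVD1, ERG26, ERG2, ERG27 and ERG10, and they span the pathway from acetyl-CoA condensation to late sterol steps. ERG5 (5.48, SE 1.02), ERG3 (3.48, SE 0.82), ERG11 (2.87, SE 0.67) and HMG1 (2.89, SE 0.55) did not pass. Without wild-type replicate 1, 10 were called, and without any other array none was. The list median was 2.39 (camera adjusted p = 5.24e-71, and adjusted p = 0.168 with an estimated correlation). ERG25 differed by 0.24 (SE 0.28) and HMG2 by 0.01 (SE 0.31).

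**Figure D2:**
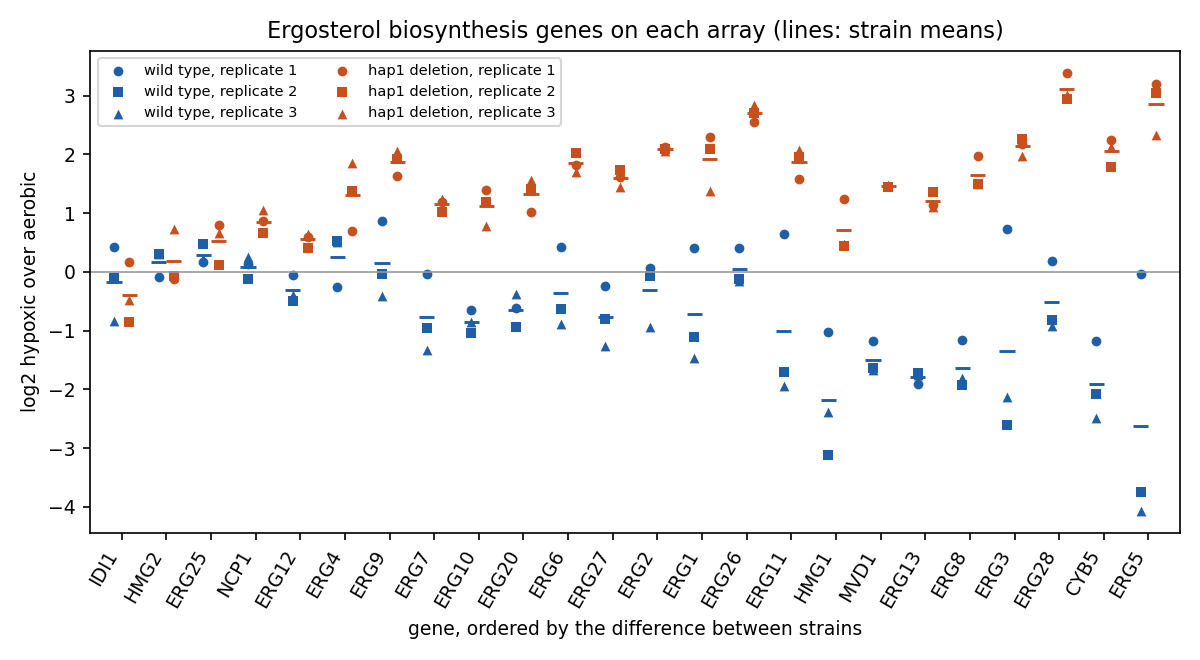
Log2 ratio, hypoxic over aerobic, of the 24 ergosterol biosynthesis genes on each array, with wild type in blue, the hap1 deletion strain in orange and a short line at each strain mean. List medians lie at -0.04, -0.88 and -0.93 on the wild-type arrays and at 1.57, 1.47 and 1.49 on the deletion arrays, and wild-type replicate 1 lies above the other wild-type arrays for ERG5, ERG3 and ERG11.

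Of the 13 textbook Hap1-activated genes YHB1, CYC1 and CYB5 differed between the strains and 10 did not pass, with 9 differing adjusted over the list alone. All 13 differences were above 0, with a median of 1.77 (camera adjusted p = 4.66e-36, and adjusted p = 0.168 with an estimated correlation). CYC7 differed by 2.49 (SE 0.59) and CYT1 by 1.77 (SE 0.44) without passing, and ROX1 by 0.74 (SE 0.37) and CYB2 by 0.46 (SE 0.41). Of 25 respiratory chain genes CYC1 passed and 24 did not, with 8 adjusted over the list alone and a median of 1.16 (camera adjusted p = 1.28e-14, and adjusted p = 0.383 with an estimated correlation).

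Outside these lists, and after OLE1, the largest differences among the genes called were those of SCM4, a mitochondrial outer membrane protein (5.08, SE 0.67), and of the membrane proteins IZH4 (3.92, SE 0.51) and IZH1 (3.23, SE 0.43). OLE1 was the only 1 of 13 fatty acid genes to pass, over all genes and adjusted over the list alone, and this list had a median of 0.25 (camera adjusted p = 0.00119, and adjusted p = 0.260 with an estimated correlation). The 3 negative differences were PTR2, a peptide transporter (1.93 ± 0.43 in wild type and -0.49 ± 0.15 in the deletion strain), IDH2 (1.67 ± 0.21 and -0.27 ± 0.23) and TIP1, a cell wall mannoprotein (1.38 ± 0.20 and -0.50 ± 0.21). IDH1 and ACO1 came next and did not pass (limma adjusted p = 0.0827 and 0.0889). With IDH2 as its only call, which was lost without any 1 of the 6 arrays, the tricarboxylic acid cycle list had 4 more negative genes adjusted over the list alone and a median of -0.22 (camera adjusted p = 3.76e-05, and adjusted p = 0.260 with an estimated correlation).

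No PAU gene passed limma's test of the difference, where 16 had an unadjusted p under 0.05, although 16 of 23 were more positive in the deletion strain adjusted over the list alone, with a median of 1.45 (camera adjusted p = 2.82e-15, and adjusted p = 0.260 with an estimated correlation). PAU6 differed by 4.24 (SE 1.20). The DAN and TIR list did not pass, with a median of -0.34 and a mean of -0.11 while camera's direction was up (camera adjusted p = 0.729). Of the 26 general stress genes none differed in limma's test, over all genes or adjusted over the list alone (2 had an unadjusted p under 0.05), with a median of -0.98 (camera adjusted p = 0.00981, and adjusted p = 0.695 with an estimated correlation). The stress list did not pass without wild-type replicate 1 or hap1 deletion replicate 1 or 2 (camera adjusted p = 0.346, 0.133 and 0.174). The a-specific mating genes differed in their oxygen response, with a median of -1.22 (camera adjusted p = 9.45e-06, and adjusted p = 0.390 with an estimated correlation). HEM13 (-1.09, SE 0.42), ANB1 (1.45, SE 0.30), COX5A (1.67, SE 0.51), COX5B (-1.39, SE 0.69), AAC3 (-1.76, SE 0.67) and TIR1 (-0.90, SE 0.52) did not pass. The HAP1 spot differed by -0.23 (SE 0.26). Its signal in the deletion strain may not come from HAP1 RNA, so this value cannot be read as a difference in the response of HAP1.

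**Figure D3:**
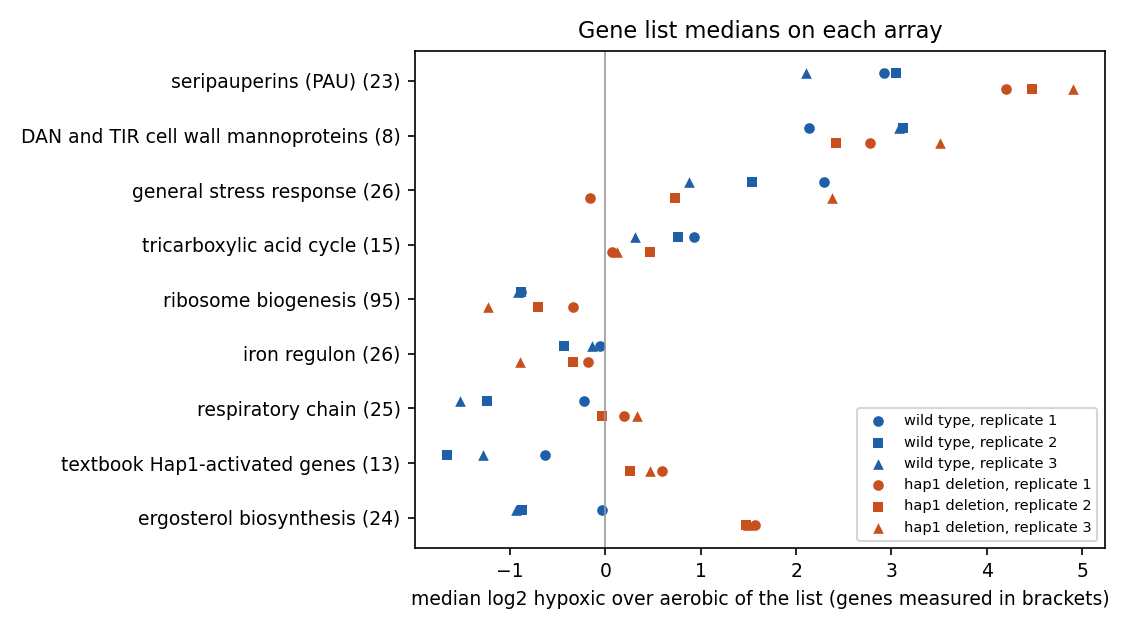
Median log2 ratio, hypoxic over aerobic, of 9 gene lists on each array, with the number of genes measured in brackets. The deletion arrays lie above the wild-type arrays for the ergosterol, Hap1-activated, respiratory chain and PAU lists, while the general stress medians of the strains overlap, with 2.29, 1.54 and 0.88 in wild type and -0.16, 0.74 and 2.37 in the deletion strain.

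The count of differences depended on single arrays: 15 positive and 1 negative were called without wild-type replicate 1, with 12 of these 16 genes among the 22, and 2 (YHB1 and CYC1) without any other array. Arrays centred and then scaled to the same spread gave 3 positive and 0 negative differences. The positive share was 100% against 86.4%, and 87% with centring alone. This scaling left 2 ergosterol genes and 1 Hap1-activated gene, CYC1, so YHB1 did not pass under it. A dye term gave 7 and 0.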

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

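The tests of explanations in this part were chosen after the results were seen. These results were picked out because limma's test of the difference between the strains (hap1 deletion minus wild type, Benjamini-Hochberg adjusted p under 0.05) called them. Groups of 3 arrays are too small to test for an outlying array.

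The genes called, with their log2 differences, fell into a few groups. The sterol genes were CYB5 (3.97), ERG28 (3.63), ERG8 (3.29), ERG13 (3.002), MVD1 (2.96), ERG26 (2.66), ERG2 (2.40), ERG27 (2.37) and ERG10 (1.97). YHB1 (5.11) and CYC1 (4.89) are textbook Hap1 targets. The others with positive differences were OLE1 (6.01), SCM4 (5.08), IZH4 (3.92), IZH1 (3.23), FHN1 (2.97), URA1 (2.70), PRM10 (2.59) and MSC7 (1.73). FHN1 is an eisosome protein that rose in both strains, by 1.27 ± 0.35 in wild type and 4.23 ± 0.41 in the deletion strain. URA1, the dihydroorotate dehydrogenase of uracil synthesis, was at -1.94 ± 0.41 in wild type and 0.76 ± 0.32 in the deletion strain. FHN1, URA1, PRM10 and MSC7 are named because all 22 calls are given. The negative differences were PTR2 (-2.42), IDH2 (-1.94) and TIP1 (-1.88).

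Of the 36 lists, 12 differed by camera with the preset correlation, and none did with an estimated correlation, where the smallest adjusted p was 0.168. Their median differences were 2.39 for ergosterol biosynthesis, 1.77 for Hap1-activated genes, 1.45 for PAU genes, 1.16 for the respiratory chain, 0.25 for fatty acid synthesis, -0.22 for the tricarboxylic acid cycle, -0.28 for other cell wall proteins, -0.28 for the proteasome, -0.33 for chaperones, -0.63 for the zinc regulon, -0.98 for general stress and -1.22 for a-specific mating genes. By fry, 4 lists passed: ergosterol biosynthesis, Hap1-activated genes and fatty acid synthesis (adjusted p = 0.00707 each) and the zinc regulon (0.0222). The other lists that camera called did not pass fry, with adjusted p from 0.0737 (tricarboxylic acid cycle) to 0.513 (general stress). Within the strains, fry passed 15 lists in wild type and 4 in the deletion strain. With 1 array left out, camera did not call chaperones without wild-type replicate 3 or hap1 deletion replicates 1 or 2 (adjusted p = 0.0800, 0.0664 and 0.174), other cell wall proteins without the same arrays (0.105, 0.230 and 0.0775), or the zinc regulon without hap1 deletion replicate 3 (0.0670).

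Of 24 sterol genes 15 rose in the deletion strain and 5 fell in wild type, and 4 (ERG13, ERG8, MVD1 and CYB5) did both, though calls in opposite directions over all genes, 5 in number, became 7, 0 and 1 without wild-type replicates 1, 2 and 3 and 3, 0 and 1 without hap1 deletion replicates 1, 2 and 3. A dye bias behind either would turn the list median over on the array with swapped dyes, but that median was 1.47 in the deletion strain (SD 0.0535 over its 3 arrays) and -0.88 in wild type (SD 0.50), while a bias shared by the strains cancels in their difference because their dye layouts were the same. An offset from centring stays open for the direction within a strain, since the arrays were centred before deposit and the difference of -0.0276 between their medians therefore decides nothing. The HAP1 deletion, the biological difference that the design names, stays open and untested beside anything else that set the strains or their culture days apart.

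A second pattern is that wild-type replicate 1 stood apart from the other wild-type arrays on sterol genes, with a list median of -0.04 against -0.88 and -0.93. The departure was not one of sterol genes alone, since medians on this array and the other wild-type arrays were -1.35 against -0.26 and -0.25 for core histones, -0.23 against -1.24 and -1.52 for the respiratory chain, -0.30 against 1.04 and 0.47 for a-specific genes and -0.60 against 0.54 and 0.44 for pheromone genes. A swap with a deletion array predicts CYC1 and YHB1 near 0, but their mean on that array was -4.79, while the lowest deletion array was at -0.20. Weaker ratios over the whole array predict a smaller spread, but the SD over all genes was 0.893 against 0.874 and 0.741. This SD holds noise as well as response, so weaker ratios on a noisier array could go unseen and the point stays open. The estimated array weight, lower for a more variable array, was 0.612 against 1.6 and 1.37. A partial mixture of RNA or a difference between culture days was not tested, and no biological explanation was tested.

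Other groupings of the arrays were also run. The real split of the 6 arrays gave 22 genes that differed and the highest of the other splits gave 0, so 1 of 10 splits reached the real count. For the responses within a strain, turning the sign of 1 array in turn gave at most 0 calls against 263 in wild type and 268 in the deletion strain, so 1 of 4 sign patterns reached the real count in each. With so few groupings no share under 0.05 is possible.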

How the results depend on the processing

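The option of leaving out both replicate 1 arrays was chosen after seeing the data; the others were set beforehand. Counts are given as higher and lower genes, in the order wild type, deletion strain and difference, against 119 and 144, 155 and 113, and 19 and 3. A dye term gave 28 and 14, 90 and 31, and 7 and 0. Estimated array weights gave 286 and 396, 319 and 348, and 31 and 4. Both replicate 1 arrays left out gave 4 and 5, 71 and 21, and 10 and 1. An adjusted p under 0.01 gave 1 and 2, 41 and 4, and 3 and 0. Each strain fitted alone, with fewer degrees of freedom, gave 0 and 2, and 73 and 11. Turning the sign of the replicate 2 arrays gave 0 throughout. Arrays centred and then scaled to the same spread gave 180 higher genes in wild type, 71 lower in the deletion strain and 3 and 0 differences. Genes with a value on all arrays gave 182 lower in the deletion strain. Leaving out 1 array gave 0 to 144 and 2 to 199, 28 to 148 and 2 to 89, and 2 to 15 and 0 to 1. The causes of these changes were not tested. Counts stayed within 1.5 times under median centring, no filter on missing values, a robust prior and a 2-fold minimum.

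The replicate number as a block gave 0 and 2, 58 and 7, and 0 and 0. Residuals of arrays with the same number correlated at -0.02, 0.06 and 0.13, and not every array correlated best with its own number, so the numbers were not taken to pair the arrays.

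With an estimated correlation camera called no list. The mean shifts, unchanged by this choice, were -0.77, 1.49 and 2.26 for ergosterol genes, -1.55, 0.67 and 2.22 for Hap1-activated genes, 2.79, 4.22 and 1.44 for PAU genes, and -1.10 in wild type and 1.25 in the difference for the respiratory chain. With replicate 2 turned, calls ended for ergosterol in wild type (-0.0871), Hap1-activated genes in all comparisons (-0.27, 0.37 and 0.65), PAU genes in wild type and the difference (0.59 and 0.92) and the respiratory chain in wild type (-0.32), and the sign reversed for the differences of cytosolic ribosomal proteins (0.21) and the proteasome (0.0393) and for CYC7 in wild type (0.20). The shift of Hap1-activated genes in the deletion strain also lost its call with array weights (0.58) and ranged from 0.55 to 0.82 with 1 array left out, without its call when hap1 deletion replicate 1 or 3 was left out. The causes were not tested.

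For 891 values of named genes and other lists, the remaining planned settings left 7228 comparisons on their side of the threshold, ended 364 calls and added 133, with none reversed. A value called in neither fit counted as staying on its side and could not be reversed. These totals therefore do not give the share of calls that were kept. Turning replicate 2 ended 164 and added 10. Leaving out 1 array ended 521 and added 72. Leaving out both replicate 1 arrays ended 113 and added 28. An alternative with each probe tested on its own was not run, since no gene had several rows. Signal over background was not used here, so its limit on these ratios is not known.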

Other observations

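The tests of the stress and mevalonate patterns in this part were chosen after the results were seen. Further genes passed limma's test. In the deletion strain URA3, the orotidine phosphate decarboxylase of uracil synthesis, rose by 4.89 ± 0.84 (limma adjusted p = 0.00163), and in wild type its mean of 1.53 ± 0.77 did not pass. HES1, an oxysterol-binding protein, rose by 2.28 ± 0.96 in wild type and by 4.54 ± 0.27 in the deletion strain. Their differences between strains did not pass (limma adjusted p = 0.0889 and 0.226). IMD2 and IMD3, which serve guanine nucleotide synthesis, fell in both strains, by 1.43 and 1.99 for IMD2 and by 1.25 and 1.79 for IMD3. URA3, HES1 and IMD3 were named after their values were seen. Of 44 amino acid synthesis genes, LYS1 rose in both strains (1.11 and 1.24), and LEU1 (1.80) and HIS4 (1.57) also rose in the deletion strain. Adjusted over the list alone, 3 rose in wild type, and 9 rose and 1 fell in the deletion strain, while the list did not pass camera (adjusted p = 0.215 and 0.0883). CIT2, the peroxisomal citrate synthase, rose in both (2.09 and 1.97), and CTA1, the peroxisomal catalase, fell in both (-0.97 and -1.06). In the phosphate regulon PHO5 and PHM6 fell in both strains among 15 genes, and the list passed in wild type and in the deletion strain (camera adjusted p = 0.0334 and 0.0443, and adjusted p = 0.597 and 0.616 with an estimated correlation). Adjusted over the list alone, 2 fell in wild type, and 5 fell and 1 rose in the deletion strain. This list did not pass in wild type without wild-type replicate 1 or 2 (camera adjusted p = 0.0992 and 0.0879), or in the deletion strain without wild-type replicate 2 or hap1 deletion replicate 3 (camera adjusted p = 0.0531 and 0.395).

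Mating genes were chosen as markers of cell type, but their ratios show only a response to oxygen and not a cell type that both cultures shared. Of 6 a-specific genes MFA2, a mating pheromone gene, fell in the deletion strain (-1.20 ± 0.36) and 5 did not pass, and none passed limma's test in wild type, where 1 had an unadjusted p under 0.05. Adjusted over the list alone, 1 rose in wild type, 1 fell in the deletion strain and 3 differed. The list differed between strains with a median of -1.22 (camera adjusted p = 9.45e-06, and adjusted p = 0.390 with an estimated correlation). AGA2, the agglutinin subunit, had 2.14 ± 1.59 in wild type and -1.11 ± 0.28 in the deletion strain without passing in any comparison. Of 4 alpha-specific and 8 pheromone genes none passed in any comparison, and of 17 meiosis genes REC8 rose in wild type, with none passing in the others. Adjusted over the list alone, 1 alpha-specific gene rose in each strain, no pheromone gene passed and 1 meiosis gene rose in wild type. Unadjusted p-values under 0.05 were found for at most 2 pheromone genes and 1 alpha-specific gene in a comparison. The smallest camera adjusted p of these 3 lists was 0.201. Without wild-type replicate 1 the a-specific and pheromone lists passed in wild type (camera adjusted p = 9.5e-05 and 0.00495), and the pheromone list also in the difference (camera adjusted p = 0.000829). The a-specific list passed in the deletion strain without wild-type replicate 1 or 2 (camera adjusted p = 0.00821 and 0.0123), where its adjusted p with all arrays was 0.0503.

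Among the other lists, glycerol metabolism had no call in limma's test in any comparison (at most 4 of 10 genes had an unadjusted p under 0.05). As a list it passed camera in wild type (adjusted p = 0.0473, and adjusted p = 0.231 with an estimated correlation), with 2 rises adjusted over the list alone, and not without any 1 of the wild-type replicates or without hap1 deletion replicate 2 (camera adjusted p = 0.0709, 0.0520, 0.111 and 0.0505). Other cell wall proteins passed in wild type, where TIP1 rose and 3 rose adjusted over the list alone (camera adjusted p = 0.0311, and adjusted p = 0.512 with an estimated correlation), but not without wild-type replicate 3 (camera adjusted p = 0.151). Sterol import and esterification had 1 call, ARE1, which rose by 1.22 in wild type, with 3 rises and 2 falls adjusted over the list alone.

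Antioxidant defence had 3 falls in wild type (YHB1, TSA1 and CTA1), 1 rise (GRX1) and 1 fall (CTA1) in the deletion strain and 1 difference (YHB1), the same counts as adjusted over the list alone. Oxygen and heme regulators had HMG1 down in wild type and SET4 up in the deletion strain (1.75), with 2 rises and 2 falls in wild type adjusted over the list alone. Gluconeogenesis and beta-oxidation had CIT2, CTA1 and, in the deletion strain, PXA1 (1.36) as calls. Sulfur metabolism had SAM2 down in wild type (-1.33) and CYS4 down in the deletion strain (-1.41). ATP synthase, hexose transporters, mitochondrial ribosomal proteins, core histones and the proteasome had no call in limma's test in any comparison. Unadjusted p-values under 0.05 were most numerous for mitochondrial ribosomal proteins in the deletion strain (13 of 66 genes). Their share was largest for core histones in wild type (3 of 8). The proteasome differed between strains by camera (median -0.28, adjusted p = 0.00981, and adjusted p = 0.714 with an estimated correlation), but not without wild-type replicate 3 or hap1 deletion replicate 1 or 2 (camera adjusted p = 0.0522, 0.121 and 0.143). With all arrays, antioxidant defence, the regulators, gluconeogenesis, beta-oxidation, sulfur metabolism, ATP synthase, hexose transporters, mitochondrial ribosomal proteins and core histones did not pass camera in any comparison. For the lists that passed camera, median, mean and direction of the test had the same sign. In wild type the antioxidant list had a median of 0.12 and a mean of -0.24, and the zinc list a median of -0.16 and a mean of 0.06. Without wild-type replicate 1 the antioxidant list passed in wild type, with a mean of -0.51 (camera adjusted p = 0.000648), and in the difference, with a mean of 0.52 (camera adjusted p = 0.00192), and it also passed in the difference without hap1 deletion replicate 1 (camera adjusted p = 0.0452). ATP synthase passed in wild type and in the difference without wild-type replicate 1 (camera adjusted p = 0.00829 and 0.0212). Mitochondrial ribosomal proteins passed in the deletion strain without hap1 deletion replicate 1 or 2 (camera adjusted p = 0.0407 and 0.0217), and in the difference without wild-type replicate 1 or hap1 deletion replicate 1 or 2 (camera adjusted p = 0.0388, 0.0298 and 0.0492). Core histones passed in wild type without wild-type replicate 2 or 3 (camera adjusted p = 0.0202 and 0.0157), gluconeogenesis in wild type without wild-type replicate 2 (0.0439), and the proteasome in the deletion strain without hap1 deletion replicate 3 (0.00993).

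Lists described earlier also passed in further comparisons with 1 array left out. In the difference these were glycolysis without hap1 deletion replicate 3 (camera adjusted p = 0.0384), cytosolic ribosomal proteins without hap1 deletion replicate 1 (0.00576) and ribosome biogenesis without hap1 deletion replicate 3 (0.00159). The iron regulon passed in the difference without wild-type replicate 2 or 3 or hap1 deletion replicate 1 or 2 (camera adjusted p = 0.00384, 0.0407, 0.0182 and 0.0480). The direction markers passed in the deletion strain without wild-type replicate 1 or 3 (camera adjusted p = 0.0175 and 0.0317) and in the difference without wild-type replicate 1 (0.0108). The overall sign was read on these markers, so their direction within a strain is not a finding.

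The stress list varied widely between arrays of a strain, and a candidate explanation is that the compared cultures differed in growth state from array to array, in which case stress and ribosome biogenesis medians would move in opposite directions. Over the 6 arrays they did so with r = -0.862 (exact permutation p = 0.0319) and Spearman's rho = -0.771 (exact permutation p = 0.103), both two-sided and the only relation computed. Without hap1 deletion replicates 1 and 3, the 2 arrays farthest from the median of the ribosome biogenesis list, r was -0.442, so the relation rests on those arrays. In wild type the medians did not move in opposite directions, with stress at 2.29, 1.54 and 0.88 and ribosome biogenesis at -0.88, -0.89 and -0.92, while in the deletion strain they did, with -0.16, 0.74 and 2.37 against -0.33, -0.71 and -1.23. Tests within a strain of 3 arrays were not run, and the explanation stays open.

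On wild-type replicate 1, genes of the mevalonate part of the sterol pathway seemed to depart less from the other wild-type arrays than later genes, which may point to separate control. The mean departure was 0.44 ± 0.63 over 9 mevalonate genes and 1.18 ± 1.22 over 15 later genes, a difference of -0.74 (exact permutation over genes, two-sided p = 0.108). The test did not pass, rests on 1 array, and treats genes as independent, so the question stays open.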
